A study of Homo sapiens with 18 samples.

How the data were processed

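Primary human hepatic stellate cells were cultured for 72 hours on cellular microarrays in DMEM with serum, RNA was taken with RNeasy columns and stranded mRNA libraries were made with a TruSeq kit, per the labels' protocols. The deposited files, 1 per library, hold expected counts per gene, the estimated reads of each gene, which the authors did not scale between libraries as far as the values show. On average 12.4% of the entries (33.4% of those above 0) were not whole numbers within a tolerance of 0.005. The genome was hg38, per the submitters' processing notes; the aligner, the counting program and whether counting used strand are not given in the sources used here. Each file lists 59526 IDs, of which 58780 are the gene IDs of GENCODE release 29, 97 are spike-in IDs and 649 are bare numbers. The spike-in and number-only IDs summed to 4 counts over all libraries and were left out. Gene symbols were found for 58207 IDs, and coordinates come from GENCODE release 29 on hg38.

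Groups and replicate numbers were taken from the titles and characteristics, giving 6 groups of 3. The total per library was 23.1 to 32.5 M counts (median 27.8 M). No 2 libraries agreed within sampling noise, as copies of 1 library would (lowest chi-square per degree of freedom 3.02), so none were merged; this does not show that they are independent cultures. The 10 most counted genes took 10.54 to 12.7% of the counts at 25 kPa and 10.04 to 12.94% at 1 kPa.

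Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr on the 6 groups kept 16384 genes, TMM factors (0.972 to 1.057) scaled the libraries, and robust quasi-likelihood F-tests were made in a model with 1 mean per group and all 18 libraries. The common biological coefficient of variation was 0.146. P-values were adjusted by Benjamini and Hochberg, and an adjusted p under 0.05 was called. Levels are TMM-normalised counts (CPM, the count divided by the effective library size in M) as mean ± SD. The 14 comparisons, fixed before the data were examined, were 25 against 1 kPa as the mean of the 3 ECM pairs and within each pair, the 3 ECM pairs against each other as the mean of the 2 stiffnesses and at each stiffness, and the interaction. "Higher" and "lower" refer to the substrate or pair named first.

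Before the data were examined, 23 gene lists were fixed: 17 pathways and 6 sets of cell type markers. The 21 with at least 5 tested genes went through camera (limma 3.58.1) against all other genes with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with the correlation estimated from the data, under which 0 of the 21 fixed lists passed in any of the 7 comparisons of lists, and fry tested whether a list's genes moved on balance in 1 direction. The fry test called 13 lists for the stiffness mean, where camera called 11. Genes named in the text followed a rule fixed in advance. It took the 8 largest rises and 8 largest falls per main comparison among called genes with a mean of at least 2 log2 CPM and the same sign in each stratum, and up to 4 members with the smallest p of each list that was called or held 2 called members. It also took the 3 largest rises and falls of each single-pair or single-stiffness comparison, up to 8 genes of the interaction, which called 0, and 13 fixed genes whatever their values. Some genes that met the rule are not printed. XIST and Y-linked genes were not considered.

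Replicate numbers recur in every group. Deviations from the group means, correlated between libraries with the same number, were all above 0.1 for C4TC with C1FN at 25 kPa (lowest 0.136) and at 1 kPa (lowest 0.114) and for FNLN with C4TC at 1 kPa (lowest 0.184). By that check the numbers pair the libraries of these comparisons, though the descriptions do not say what a number stands for; a replicate block changed none of their calls.

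Alternatives planned in advance were RLE size factors, library size only, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, a replicate block, only the groups compared, and each library left out in turn; for lists also the estimated correlation, fry and a block in camera. Added after the data were seen were the 6 libraries numbered 2 left out, limma-voom with sample quality weights, and the block together with the estimated correlation or with fry. Simulated data were drawn from the real means, with 1 spread per gene in all groups and no effect of the replicate number. The pipeline was tested on them with 200 changed genes of at least 1 CPM, 50 per fold. For the stiffness mean (16150 genes) it recovered 40% of 1.25-fold, 74% of 1.5-fold, 96% of 2-fold and 98% of 3-fold changes, and called 0.031% of unchanged genes. For stiffness on C1FN (16166 genes) the shares were 8%, 58%, 80% and 96%, for C4TC against C1FN as the mean (16155 genes) 36%, 60%, 88% and 96%, and at 1 kPa (16153 genes) 6%, 46%, 80% and 96%. In these 3 it called 0.044 to 0.056% of unchanged genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.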

Results

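Human hepatic stellate cells, the liver cells that turn into matrix-producing myofibroblasts in fibrosis, were grown for 72 hours on microarray substrates with a stiffness of 25 or 1 kPa. Each substrate carried 1 of 3 pairs of extracellular matrix (ECM) proteins: collagen 1 with fibronectin (C1FN), collagen 4 with tenascin C (C4TC) or fibronectin with laminin (FNLN). Polyadenylated RNA of the 6 combinations was sequenced in 3 libraries per group, numbered 1 to 3, 18 libraries in all. The total per library was 23.1 to 32.5 M counts (median 27.8 M), with 21424 to 22781 genes counted at least once. The comparisons address how ECM composition and stiffness change gene expression in activated stellate cells. GEO's descriptions do not say whether the 3 libraries of a group came from separate donors or cultures, so p-values measure the spread between these samples, which may be technical.

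Stiffness separated the libraries along the largest axis of variation, and replicate numbers along the next. The first principal component held 36.8% of the variance, with group means ± SD (n = 3) at 25 kPa of 30.5 ± 2.4 for C1FN, 31 ± 2.7 for C4TC and 28.8 ± 1.3 for FNLN. At 1 kPa the means were -23.4 ± 16.4, -42.9 ± 24.3 and -24 ± 17.4, so the soft libraries were spread far more widely than the stiff ones. On the component that held 9.6% of the variance, libraries numbered 1 lay apart from those numbered 2 and 3 at both stiffnesses. At 1 kPa the libraries numbered 2 lay farthest from the stiff libraries on the first component in each of the 3 ECM pairs, and those numbered 1 lay nearest. Mitochondrially encoded genes took 3.32 to 4.39% of the counts at 25 kPa and 2.47 to 3.46% at 1 kPa. Ribosomal protein genes took 2.89 to 3.32% and 2.49 to 2.97%.

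**Figure D1:**
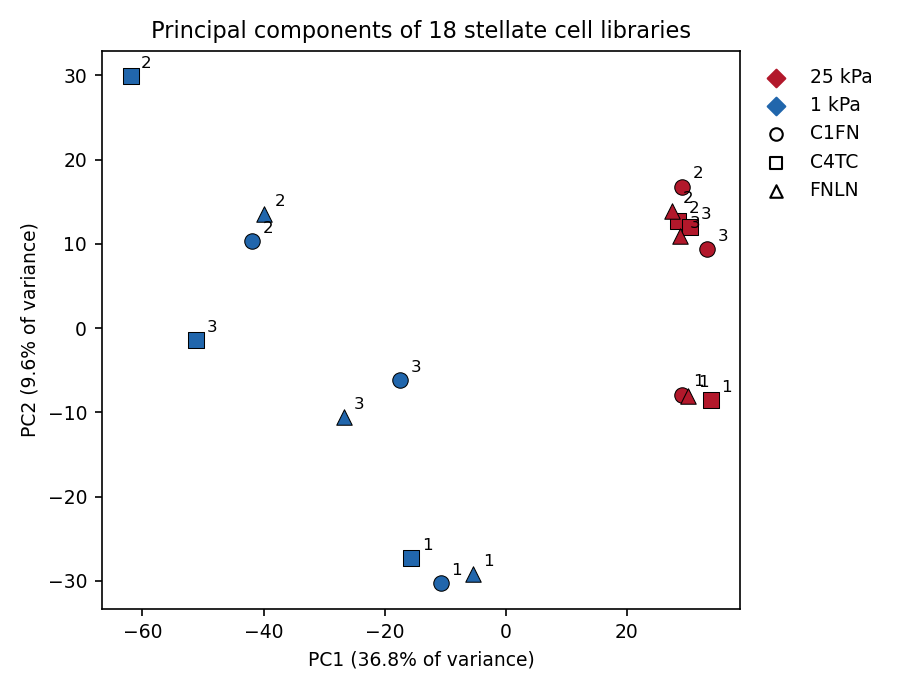
Principal components of the 18 libraries, with PC1 (36.8% of variance) on the x axis and PC2 (9.6%) on the y axis; colour gives stiffness, shape the ECM pair and the digit the replicate number. The 9 stiff libraries sit between 27.5 and 33.9 on PC1, and the 9 soft ones between -62 and -5.4.

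On the stiffer substrate most tested genes of contractile proteins and YAP/TAZ targets were higher, and most of cytokines, matrix proteases with their inhibitors, and basement membrane proteins were lower. As lists these passed camera with a preset correlation between genes, while 0 of 21 lists passed with an estimated one. Averaged over the 3 ECM pairs, 6442 of 16384 genes changed between 25 and 1 kPa, 3192 higher and 3250 lower at 25 kPa (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 303 were at least 2-fold higher and 496 at least 2-fold lower. The direction was the same in all 3 ECM pairs for 6385 of the changed genes (99.1%). For 1996 of the 16384 tested genes (12.2%) the 9 stiff and 9 soft libraries did not overlap, where chance gives 0.00411% of genes. Within the 6 libraries that share a replicate number, 3 stiff against 3 soft, 5521, 4058 and 4357 genes changed for numbers 1, 2 and 3. In these fits the 3 ECM pairs served as the replicates. What a number stands for is not given, so the counts are not shown to be independent repeats.

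Among genes with a mean of at least 2 log2 CPM and the same sign in every ECM pair, the largest rise was in ANKRD1 (ENSG00000148677.6; chromosome 10, 90912096 to 90921276, hg38). This protein-coding gene encodes a muscle ankyrin repeat protein and is a standard readout of YAP/TAZ activity. Its normalised count was 71.9 ± 11.9 CPM at 25 kPa and 10.4 ± 6.2 CPM at 1 kPa (SD, n = 9), 7.02-fold higher on the stiff substrate (log2 fold change 2.81, SE 0.35, adjusted p = 2.09e-05, edgeR). MEST, an imprinted gene (ENSG00000106484.15; chromosome 7, 130486171 to 130506465), was at 18.8 ± 3.14 and 3.44 ± 2.09 CPM (log2 fold change 2.53). The next largest rises were in MAP3K7CL (1.99), the forkhead factor FOXS1 (1.99), PPP1R14A (1.98), RGS5 (1.84), HAPLN1 (1.83) and CDK15 (1.81). PPP1R14A encodes an inhibitor of myosin phosphatase in smooth muscle, RGS5 a G-protein regulator of pericytes, and HAPLN1 a link protein of hyaluronan matrix. All 8 were higher in each of the 9 stiff libraries than in any soft one.

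By the same limits on level and sign, the 8 largest falls included 6 genes of cytokines and chemokines. IL24 (ENSG00000162892.15, chromosome 1, 206897443 to 206904139), a cytokine gene, was at 2.91 ± 3.03 CPM at 25 kPa and 88.6 ± 64.4 CPM at 1 kPa. It was 31.6-fold lower on the stiff substrate (log2 fold change -4.98, SE 0.59, adjusted p = 1.32e-05, edgeR). The log2 fold change was -5.76 without C1FN 25 kPa replicate 1, and -3.04, -7.46 and -4.83 within replicate numbers 1, 2 and 3. PTPRN, which encodes a phosphatase-like protein of secretory granules, fell from 28.3 ± 18.5 to 0.892 ± 0.199 CPM between soft and stiff (log2 fold change -4.92). The alarmin IL33 (-4.41), the fibroblast cytokine IL11 (-4.37), the neutrophil-attracting chemokines CXCL5 (-4.28), CXCL2 (-4.20) and CXCL3 (-4.15), and the stromelysin MMP3 (-4.25) completed the 8. In all 8 the stiff and soft libraries did not overlap. CXCL1, CXCL2 and CXCL3, like ACTA2 and ACTG2, have closely similar sequences; how the authors' counting shared reads between copies is not given in the sources used here, so their separate levels are uncertain.

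Contractile genes rose together: of 19 tested, 17 rose at 25 kPa, 0 fell and 2 (MYH11 and LPP) did not pass, and 17 rose when adjusted over the list alone. ACTA2, the smooth muscle actin that marks activated stellate cells (chromosome 10, 88935074 to 88991339), was at 716.1 ± 101.6 CPM at 25 kPa and 366.8 ± 166.2 CPM at 1 kPa (SD, n = 9; log2 fold change 1.07, SE 0.2, adjusted p = 0.000605, edgeR). Its stiff and soft libraries overlapped. Within replicate numbers 1, 2 and 3 its log2 fold changes were 0.59, 1.65 and 1.15, none of which passed (adjusted p = 0.0533, 0.209 and 0.222, edgeR). TAGLN, an actin-binding protein of smooth muscle, was at 2907 ± 160 and 1711 ± 506 CPM (log2 fold change 0.80). The myosin light chain MYL9 rose by 0.72, the tropomyosin TPM2 by 0.70 and the enteric actin ACTG2 by 1.58 on the log2 scale. The median over the list was 0.70, and camera ranked it above other genes (adjusted p = 4.78e-08), but adjusted p = 0.28 with an estimated correlation.

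Of 23 YAP/TAZ targets, 16 rose, 1 (NT5E) fell and 6 did not pass, with 17 and 1 when adjusted over the list alone. Besides ANKRD1, the receptor kinase AXL rose from 280 ± 52.6 to 430.8 ± 29.7 CPM between soft and stiff (log2 fold change 0.62) and IGFBP3 by 1.28. CCN2, also called CTGF, was at 1762 ± 251 CPM at 25 kPa and 977.9 ± 487.6 CPM at 1 kPa (log2 fold change 0.86, adjusted p = 0.0267, edgeR). That call ended without C1FN 25 kPa replicate 3 (0.0524), C4TC 25 kPa replicate 1 (0.0504), C4TC 1 kPa replicate 3 (0.0515) or the filter on low counts (0.0868). CCN1, also called CYR61, did not pass (log2 fold change 0.48, adjusted p = 0.13). Its direction differed between replicate numbers 1, 2 and 3, with log2 fold changes of -0.15, 1.34 and 0.65 (adjusted p = 0.0178, 0.0101 and 0.0649, edgeR). The median of these targets was 0.51 (camera, adjusted p = 4.57e-06; adjusted p = 0.384 with an estimated correlation). Among 17 SRF/MRTF targets, 7 rose and 5 fell (8 and 5 adjusted over the list alone). The 5 that fell were the immediate early genes FOS (-1.65), FOSB, EGR2 (-1.59), EGR3 and JUNB (-1.02), while FHL1 (0.69) and the actin genes ACTB and ACTG1 rose. The SRF/MRTF median was 0.15, the mean -0.25 and its camera direction down (adjusted p = 0.783).

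Cytokine and inflammatory genes were lower on the stiff substrate almost throughout the list. Of 27 tested, 0 rose, 25 fell and 2 (CXCL12 and CSF2) did not pass, with 26 lower when adjusted over the list alone. IL6 was at 72.9 ± 23.7 CPM at 25 kPa and 477 ± 119 CPM at 1 kPa, 6.56-fold lower (log2 fold change -2.71, SE 0.2, adjusted p = 2.11e-07, edgeR). SOD2, the mitochondrial superoxide dismutase induced by NF-kB, was at 239.9 ± 34.1 and 1227 ± 248 CPM (-2.35), the adhesion receptor ICAM1 at 44.5 ± 2.86 and 94.2 ± 10.9 CPM (-1.08), and the chemokine CCL7 at 0.366 ± 0.115 and 8.59 ± 4.48 CPM (-4.50). The median cytokine log2 fold change was -2.03, the lowest of the 21 lists tested (camera, adjusted p = 2.77e-24; adjusted p = 0.0724 with an estimated correlation). The median was -1.12, -2.65 and -2.38 within replicate numbers 1, 2 and 3. Interferon response genes had 2 of 19 members higher, 0 lower and 0 called when adjusted over the list alone (median 0.45, and 0.54, 0.97 and -0.04 within the 3 numbers; camera, adjusted p = 0.0781). These were IFIT2 (0.77, adjusted p = 0.0222, edgeR) and IFI27 (1.13, adjusted p = 0.0264), beside IFIT1 (0.96, adjusted p = 0.0595) and IFIT3 (0.45, adjusted p = 0.0904). The IFIT2 call ended without C4TC 25 kPa replicate 1 (0.056) or FNLN 25 kPa replicate 2 (0.0567), and the IFI27 call without C1FN 25 kPa replicate 2 (0.076), C4TC 25 kPa replicate 1 (0.062), FNLN 25 kPa replicate 1 (0.052) or FNLN 1 kPa replicate 2 (0.0514). Both also ended without the filter on low counts (0.0783 and 0.0846) and without the libraries numbered 2 (0.317 and 0.245). Camera passed the interferon list without any of C1FN 25 kPa replicate 3 (0.016), C4TC 25 kPa replicates 2 (0.0245) and 3 (0.0167), FNLN 25 kPa replicate 3 (0.0382), C1FN 1 kPa replicate 3 (0.0409), C4TC 1 kPa replicate 1 (0.0141) or FNLN 1 kPa replicate 3 (0.0188).

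**Figure D2:**
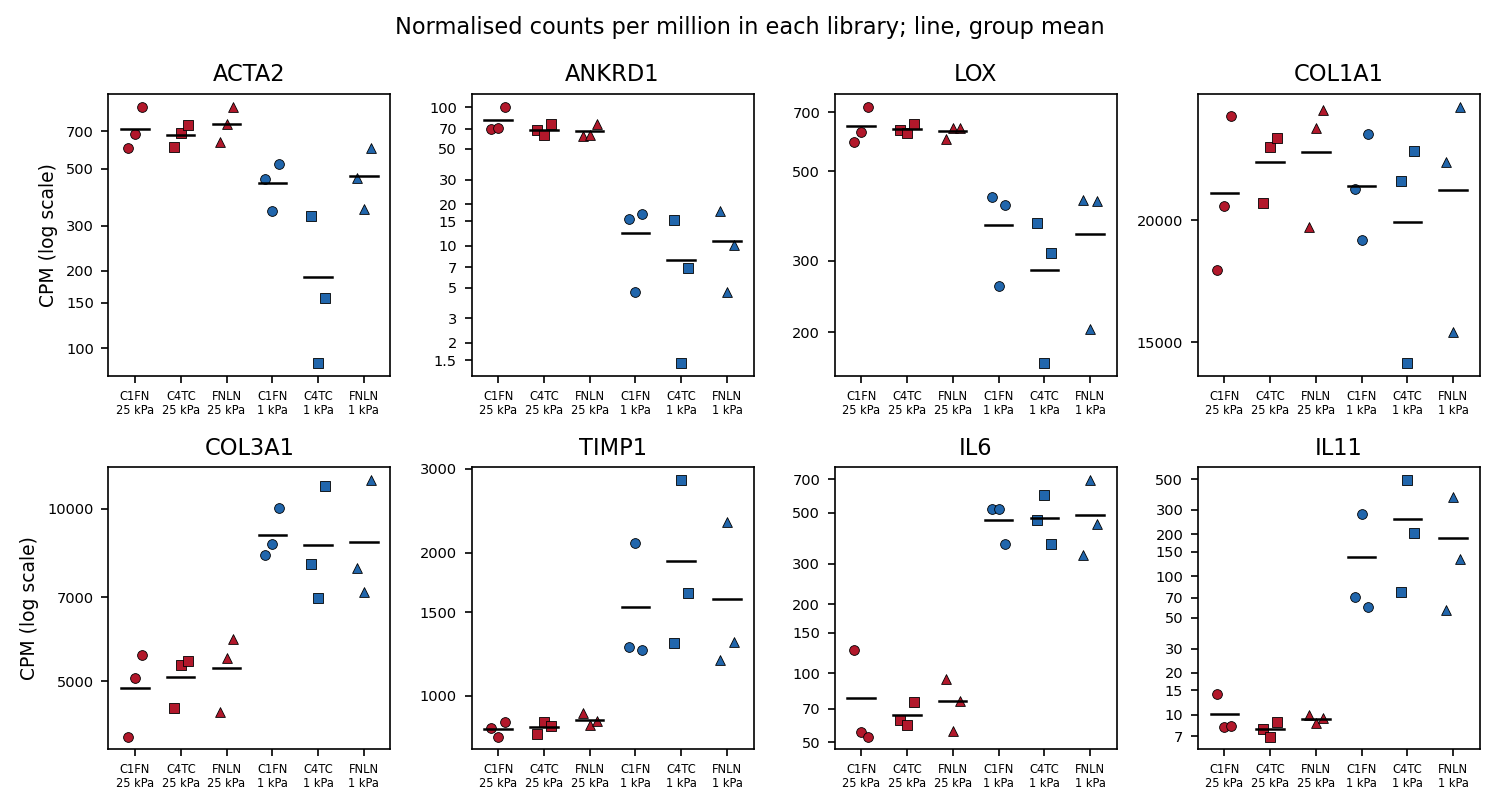
Normalised counts in CPM (y axis, log scale) of 8 genes in each of the 18 libraries, by ECM pair and stiffness (x axis); points are libraries and lines are group means of 3. IL6, IL11, COL3A1 and TIMP1 were lower and ANKRD1 and LOX higher in each of the 9 stiff libraries than in any soft one, while ACTA2 and COL1A1 overlapped.

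Genes of collagen chains fell or did not pass, and the 3 rises in their list were in processing enzymes. Of 26 fibrillar collagens and collagen-processing enzymes, 3 rose and 14 fell, with 4 and 16 when adjusted over the list alone. These 3 were the cross-linking oxidases LOX, LOXL1 and LOXL4; LOX was at 636.8 ± 37.8 CPM at 25 kPa and 334.3 ± 102.3 CPM at 1 kPa (log2 fold change 0.94, adjusted p = 0.000341, edgeR). COL3A1 fell from 8802 ± 1570 to 5076 ± 635.6 CPM between soft and stiff (log2 fold change -0.80, adjusted p = 3.42e-05). The prolyl hydroxylase subunit P4HA3 (-1.58), COL6A2 (-0.51), the procollagen C-proteinase enhancer PCOLCE (-0.60) and COL16A1 (-0.65) fell too. COL1A1, the main fibrillar collagen of scar, was at 22610 ± 2930 and 21050 ± 4049 CPM and did not pass (log2 fold change 0.10, SE 0.12, adjusted p = 0.52). Its direction differed between replicate numbers, with log2 fold changes of -0.19, 0.50 and 0.03 for numbers 1, 2 and 3. The median of the collagen list was -0.25 (camera, adjusted p = 0.000241; adjusted p = 0.458 with an estimated correlation), and -0.32, 0 and -0.36 within replicate numbers 1, 2 and 3.

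Basement membrane genes fell in 13 of 19 cases and rose in 0, with 13 and 0 when adjusted over the list alone. LAMA4, a laminin alpha chain, was at 95.6 ± 6.3 CPM at 25 kPa and 249.7 ± 35 CPM at 1 kPa (log2 fold change -1.39, adjusted p = 5.87e-09, edgeR). COL4A6 (-0.85), COL18A1 (-0.41), the nidogen NID2 (-0.39) and LAMB1 (-0.45) fell. COL4A1, a chain of the collagen 4 used as substrate, did not pass (0.09, adjusted p = 0.675), and without C4TC 1 kPa replicate 2 its log2 fold change was -0.002. Within replicate numbers 1, 2 and 3 it was -0.3, 0.68 and 0.02 (adjusted p = 0.000328, 0.0365 and 0.909, edgeR), so its direction differed between them. The basement membrane median was -0.35 (camera, adjusted p = 1.86e-07; adjusted p = 0.202 with an estimated correlation). In the 26 matrix glycoproteins and proteoglycans, 3 rose and 12 fell (5 and 12 adjusted over the list alone; median -0.13, camera adjusted p = 0.128, and 0.0412 without C4TC 1 kPa replicate 2). Their median was -0.26, 0.17 and -0.22 within replicate numbers 1, 2 and 3. Fibromodulin FMOD (-1.96), the microfibril protein MFAP4 (-1.47), the TGF-beta-binding protein LTBP1 (-0.40) and TNC, tenascin C (-0.63; 209.1 ± 25.6 and 330.5 ± 87.4 CPM), were lower at 25 kPa. FN1, fibronectin, was at 28330 ± 3066 and 22600 ± 5646 CPM and did not pass (0.33, adjusted p = 0.058).

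Matrix proteases and their inhibitors fell in 14 of 22 cases, with 1 rise (PLAT), and 15 and 3 when adjusted over the list alone. The gelatinase MMP2 was at 3634 ± 132 CPM at 25 kPa and 6449 ± 602 CPM at 1 kPa (log2 fold change -0.83, adjusted p = 1.85e-08, edgeR), and the membrane protease MMP14 at 1931 ± 118 and 3626 ± 485 CPM (-0.90). The inhibitors TIMP1 (-0.95; 867.3 ± 29.8 and 1688 ± 594 CPM) and TIMP2 (-0.36) fell with them, as did MMP10 (-2.32). The protease list had a median of -0.48 (camera, adjusted p = 1.2e-07; adjusted p = 0.0724 with an estimated correlation). Integrin and adhesion genes split, with 10 of 27 higher and 10 lower (12 and 11 adjusted over the list alone; median -0.02, camera adjusted p = 0.659). The collagen receptor chains ITGA1 (-0.77) and ITGA2 (-1.12) and ITGB3 (-0.97) fell, and the laminin receptor chain ITGA7 rose (0.94).

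Of 18 TGF-beta response genes, 2 rose (CCN2 and TGFB1I1) and 10 fell, with the same counts when adjusted over the list alone. PMEPA1, a negative regulator of the pathway, fell by 2.46 on the log2 scale, the cartilage matrix protein COMP by 1.73 and the repressor BHLHE40 by 0.60, beside IL11. The TGF-beta list had a median of -0.28 (camera, adjusted p = 0.000254; adjusted p = 0.0724 with an estimated correlation). The list fixed in advance as quiescent stellate cell genes went both ways, 5 of 14 higher and 4 lower, and the same when adjusted over the list alone. Whether each member marks quiescence in these cells was not tested, so the split is not a reading of quiescence. RGS5, ADIRF (1.05) and the intermediate filament NES (0.81) rose, and CYGB, the globin of stellate cells, fell (-1.91). The quiescent list's median was -0.15 and its mean -0.02, while camera's direction was up (adjusted p = 0.314).

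Cholesterol synthesis genes were lower on the stiff substrate: 17 of 22 fell and 0 rose, with 18 and 1 when adjusted over the list alone. DHCR7 (-0.70) and CYP51A1 (-0.63), enzymes of the pathway, were among them. The cholesterol list had a median of -0.49 (camera, adjusted p = 2.72e-08; adjusted p = 0.325 with an estimated correlation). Cell cycle genes were higher in 12 of 32 cases and lower in 0, with 12 and 0 when adjusted over the list alone (median 0.33; camera, adjusted p = 0.00312; adjusted p = 0.746 with an estimated correlation). Mitotic genes CCNB2 (0.63, adjusted p = 0.00949, edgeR), CCNB1 (0.56, 0.0116) and CDC20 (0.60, 0.0134), and CCNE2 (0.41, 0.0149), were among them. The CDC20 call ended without the filter on low counts (0.0528). With the 6 libraries numbered 2 left out, 0 cell cycle genes passed, while the list's median was 0.28. With a replicate block 24 were higher and 1 lower, though the stiffness comparisons did not meet the check for pairing. The list's median was 0.21, 0.4 and 0.42 within replicate numbers 1, 2 and 3.

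Glycolysis and hypoxia genes had 9 of 19 members higher and 6 lower, also when adjusted over the list alone. The angiogenic factor VEGFA was at 96.3 ± 12.5 CPM at 25 kPa and 269.2 ± 98.8 CPM at 1 kPa (log2 fold change -1.47, adjusted p = 1.36e-05, edgeR), and NDRG1 (-0.67), PFKFB3 (-0.55) and ALDOC (-0.51) fell. The median was 0.11, the mean -0.14 and camera's direction down (adjusted p = 0.691). Endoplasmic reticulum and amino acid stress genes had 2 of 19 higher and 5 lower, also when adjusted over the list alone. The chaperones HYOU1 (-0.36), PDIA4 (-0.19) and DNAJB9 (-0.52) fell and asparagine synthetase ASNS rose (0.88); the median was 0.09 with camera's direction down (adjusted p = 0.834). Of 16 p53 targets, 1 rose and 2 fell (0 and 2 adjusted over the list alone; median 0.00, mean -0.03, camera adjusted p = 0.497). The stress cytokine GDF15 (-0.75) and the death receptor TNFRSF10B (-0.38) fell. DDB2 was at the threshold (0.12, adjusted p = 0.047), beside XPC (-0.14, adjusted p = 0.0504). The DDB2 call held without C1FN 25 kPa replicate 2, FNLN 25 kPa replicate 1, C1FN 1 kPa replicate 3, C4TC 1 kPa replicate 1 or FNLN 1 kPa replicate 2, and ended without any other library, and with RLE factors, limma-voom, no filter on low counts or no libraries numbered 2 (adjusted p 0.0501 to 0.176 over the settings that ended it).

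**Figure D3:**
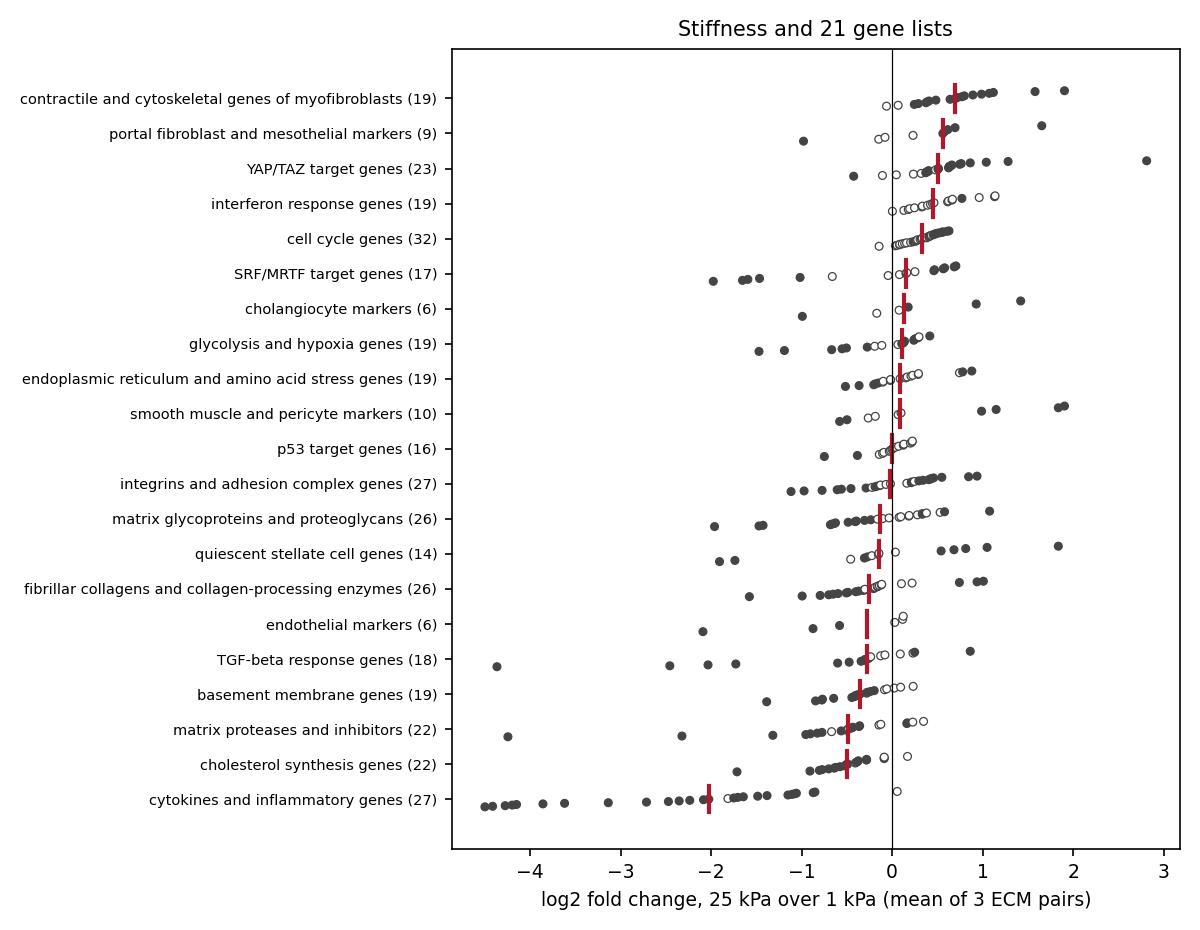
Log2 fold change (x axis, 25 over 1 kPa, mean of 3 ECM pairs) of each tested gene in the 21 lists with at least 5 tested genes (y axis, number tested in parentheses); filled points passed edgeR's test, open points did not, and bars are list medians. Medians ran from -2.03 for cytokines to 0.70 for contractile genes.

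Markers of other liver cell types were low or went both ways. Of the hepatocyte markers 2 were tested: APOA1 rose (0.60) and SERPINA1 did not pass (-0.60), and both were called when adjusted over the list alone. The macrophage and leukocyte markers also had 2 tested, of which CD68 fell (-0.77) and CD14 did not pass, also when adjusted over the list alone. Cholangiocyte markers had 3 of 6 higher and 1 lower (3 and 2 adjusted over the list alone; median 0.13, camera adjusted p = 0.288), with the keratins KRT19 (1.42) and KRT7 (0.93) and ANXA4 (0.18) higher and SOX9 lower (-0.99). Endothelial markers had 0 of 6 higher and 3 lower, also over the list alone (median -0.28, camera adjusted p = 0.0973, and 0.0363 without C4TC 1 kPa replicate 2). PECAM1 was at 0.754 ± 0.251 CPM at 25 kPa and 3.26 ± 1.57 CPM at 1 kPa (-2.09); KDR (-0.58) and VWF (-0.87) fell, and CDH5 did not pass (0.12, adjusted p = 0.444, edgeR). Portal fibroblast and mesothelial markers had 5 of 9 higher and 1 lower, with 6 and 1 when adjusted over the list alone (median 0.56; camera, adjusted p = 0.0251; adjusted p = 0.325 with an estimated correlation). KRT18 (1.65; 384.3 ± 64.1 and 124.3 ± 50.9 CPM), KRT8 (0.56) and THY1 (0.61) rose and CALB2 fell (-0.98). Smooth muscle and pericyte markers, of which CNN1, DES and MYH11 are also in the contractile list and RGS5 in the quiescent list, had 4 of 10 higher and 2 lower, also over the list alone. CSPG4 (1.15), CNN1 (0.99) and RGS5 rose and PDGFRB fell (-0.58); the median was 0.08 (camera, adjusted p = 0.0214; adjusted p = 0.274 with an estimated correlation).

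The stiffness change was then read within each ECM pair. On C4TC, 3692 genes changed (1658 higher and 2034 lower at 25 kPa), on C1FN 1809 (696 and 1113) and on FNLN 1355 (477 and 878; edgeR's quasi-likelihood test). The largest rises and falls given here follow the rule for named genes. ANKRD1 was among the 3 largest rises on each pair, with log2 fold changes of 2.70 on C1FN (adjusted p = 0.0105, edgeR), 3.11 on C4TC (0.00264) and 2.63 on FNLN (0.0151). MEST rose by 2.30, 3.16 and 2.13, and the other leading rises were RGS5 on C1FN (2.0), MAP3K7CL on C4TC (2.53) and FOXS1 on FNLN (1.82). Among the falls, IL24 had log2 fold changes of -4.21, -5.95 and -4.78 and PTPRN of -4.67, -5.79 and -4.30. The other gene among the 3 largest falls was CXCL5 on C1FN (-3.86), IL33 on C4TC (-5.32) and IL11 on FNLN (-4.32). IL6 was lower on each pair, with -2.58, -2.86 and -2.70 (adjusted p = 0.000459, 0.000105 and 0.000554). ACTA2 passed on C4TC (log2 fold change 1.84, adjusted p = 0.00212) but not on C1FN (0.71, adjusted p = 0.213) or FNLN (0.68, adjusted p = 0.259), and TAGLN likewise (1.24, 0.59 and 0.57; adjusted p = 0.00116, 0.0979 and 0.131). Among contractile genes 2 of 19 rose on C1FN, 14 on C4TC and 2 on FNLN, with list medians of 0.58, 0.96 and 0.46 (camera, adjusted p = 2.25e-05, 6.39e-12 and 3.45e-05; adjusted p = 0.387, 0.228 and 0.431 with an estimated correlation). Cytokine genes fell in 16, 24 and 17 of 27 cases, with medians of -1.86, -2.21 and -2.20 (adjusted p = 0.0835, 0.114 and 0.0798 with an estimated correlation).

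These counts depended on single libraries and on the processing. The planned replicate block raised all 3, with the values given in the section on processing, though these comparisons did not meet the check for pairing. Without the 6 libraries numbered 2, a fit chosen after the data were seen, they were 381 on C1FN, 2285 on C4TC and 829 on FNLN. With quality weights, also chosen then, C4TC gave 6648 and FNLN 3088, and with only the groups compared 2086 and 829. The C1FN count was 1068 without C1FN 25 kPa replicate 1, 886 without replicate 2 and 745 without C1FN 1 kPa replicate 2. The C4TC count was 2136 without C4TC 1 kPa replicate 3. The FNLN count was 722, 768 and 614 without FNLN 25 kPa replicates 1, 2 and 3, and 651 without FNLN 1 kPa replicate 3. Single-pair calls of named genes ended in the same way: ANKRD1 on C1FN without C1FN 1 kPa replicate 2 (adjusted p = 0.0537, edgeR), and on FNLN without FNLN 1 kPa replicate 2 (0.0548) or 3 (0.0659). IL24 on C1FN ended without C1FN 25 kPa replicate 2 (0.055) or C1FN 1 kPa replicate 2 (0.06), and IL24 (0.0524) and MEST (0.0558) on FNLN without FNLN 25 kPa replicate 3. CXCL5 on C1FN ended without C1FN 25 kPa replicate 2 or 3 or C1FN 1 kPa replicate 2. Other settings ended calls too: for CXCL5 on C1FN limma-voom (0.13; 0.0752 with quality weights), no filter on low counts (0.0703), only the groups compared (0.127) and no libraries numbered 2 (0.125), for IL24 on C1FN the latter 2 (0.122 and 0.0883), for ANKRD1 on FNLN no filter (0.0532) and for FOXS1 on FNLN no libraries numbered 2 (0.15). Folds moved by over 1.5 times as well: on C1FN, IL24 was at -6.56 and CXCL5 at -5.06 on the log2 scale without C1FN 25 kPa replicate 1, and IL24 at -3.46, CXCL5 at -2.76 and PTPRN at -3.92 without C1FN 1 kPa replicate 2. On C4TC, ANKRD1 was at 4.04 and MEST at 3.79 without C4TC 1 kPa replicate 1, and IL24 at -5.09 and IL33 at -4.70 without replicate 2. On FNLN, IL24 was at -5.56 without FNLN 25 kPa replicate 1, and at -3.84 with IL11 at -3.33 without FNLN 1 kPa replicate 2. Correlations of the log2 fold changes across 16384 genes, which are not independent replicates, were 0.622 between C1FN and C4TC, 0.625 between C1FN and FNLN and 0.655 between C4TC and FNLN. No libraries are shared between these comparisons, but they share 1 fit, its estimate of each gene's spread and the replicate numbers. In the same order, 1609, 1102 and 1269 genes were called in both, all with the same sign. Independent lists would share 209, 80 and 157 with the same sign, which is only a loose reference because the calls are not independent.

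Whether the stiffness change differed between ECM pairs was tested as an interaction, and 0 genes passed (edgeR's quasi-likelihood test; 199 at an unadjusted p under 0.05), with 2 by DESeq2, 0 by limma-voom and 1 by edgeR without C4TC 1 kPa replicate 1. The pairwise differences of the stiffness changes also gave 0 genes, with 324 (C4TC minus C1FN), 146 (FNLN minus C1FN) and 314 (FNLN minus C4TC) at an unadjusted p under 0.05. For ACTA2 the change on C4TC exceeded that on C1FN by 1.13 on the log2 scale (SE 0.49, unadjusted p = 0.0344, adjusted p = 1, edgeR). The contractile list's median difference was 0.38 for C4TC minus C1FN (camera, adjusted p = 1.02e-11; adjusted p = 0.557 with an estimated correlation). For FNLN minus C4TC it was -0.44 (camera, adjusted p = 3.59e-13; adjusted p = 0.3 with an estimated correlation). This was not particular to contractile genes: for C4TC minus C1FN the median difference was -0.36 in cholesterol genes (camera, adjusted p = 1.02e-11), 0.57 in interferon response genes (2.19e-06) and 0.25 in YAP/TAZ targets (0.00132), with adjusted p = 0.557, 0.616 and 0.616 with an estimated correlation.

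Between ECM pairs at equal stiffness few genes passed, which does not show that the cells were alike. At an unadjusted threshold of 0.05, chance alone would pass a share of 0.05 of the genes. Every count at an unadjusted p under 0.05 given for ECM pairs or the interaction lay below that share, so none is evidence of weak differences. At 1 kPa the fitted log2 difference was under 0.5 for at least 98.2% of genes in each comparison. Among 11276 genes with a mean of at least 2 log2 CPM, the largest there was 1.8 for C4TC with C1FN, 1.72 for FNLN with C4TC and 0.88 for FNLN with C1FN. For C4TC against C1FN, averaged over both stiffnesses, 0 of 16384 genes passed edgeR's quasi-likelihood test (515 at an unadjusted p under 0.05), with 0 by DESeq2 and 0 by limma-voom; without C4TC 1 kPa replicate 1 edgeR called 4. Contractile genes were lower on C4TC as a list, with a median log2 fold change of -0.25 (camera, adjusted p = 4.13e-11; adjusted p = 0.691 with an estimated correlation), and 0 of its 19 members passed, also when adjusted over the list alone. The named members had fitted values of -0.59 (CNN1), -0.78 (ACTG2), -0.65 (ACTA2, SE 0.24) and -0.22 (MYL9), each with an adjusted p of 1. The list's median was -0.06 at 25 kPa and -0.43 at 1 kPa, where ACTA2 was at 190.1 ± 123.3 CPM on C4TC and 440.4 ± 91.3 CPM on C1FN (SD, n = 3; log2 fold change -1.21, adjusted p = 1, edgeR). Cholesterol genes were higher on C4TC as a list, with a median of 0.18 (camera, adjusted p = 2.25e-11; adjusted p = 0.691 with an estimated correlation), and fitted values of 0.26 (DHCR7) and 0.25 (MVD). The cholesterol median was 0 at 25 kPa and 0.35 at 1 kPa. Both list calls held in the 18 fits without 1 library.

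Smaller list differences between C4TC and C1FN rested on single libraries. Matrix glycoproteins and proteoglycans (median -0.10; camera, adjusted p = 0.00586; adjusted p = 0.691 with an estimated correlation) held ASPN (-0.47), TNC (-0.22), POSTN (-0.24) and FBLN5 (-0.16). That call ended without C1FN 25 kPa replicate 3 (0.149), C1FN 1 kPa replicate 3 (0.0794) or C4TC 1 kPa replicate 2 (0.256). YAP/TAZ target genes (median -0.11; camera, adjusted p = 0.0103; adjusted p = 0.743 with an estimated correlation) held NUAK2 (-0.27), IGFBP3 (-0.45), CCDC80 (-0.23) and ANKRD1 (-0.43). Their call ended without C1FN 25 kPa replicate 3 (0.0699), C4TC 25 kPa replicate 2 (0.0931), C1FN 1 kPa replicate 1 (0.28) or C4TC 1 kPa replicate 2 (0.986, with the direction up). ANKRD1 ranged from -0.898 without C4TC 1 kPa replicate 1 to -0.187 without replicate 2, and CCDC80 from -0.382 to -0.094 likewise. Cytokines and inflammatory genes (median 0.09; camera, adjusted p = 0.0124; adjusted p = 0.743 with an estimated correlation) held CCL5 (0.73), CCL7 (0.59), IL1A (0.30) and LIF (0.29). This call ended without C1FN 25 kPa replicate 2 (0.209) or 3 (0.349), C4TC 25 kPa replicate 1 (0.101), C1FN 1 kPa replicate 3 (0.234) or C4TC 1 kPa replicate 2 (0.43). None of these members passed edgeR's test.

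Averaged over stiffness, FNLN and C1FN gave the closest profiles of the 3 comparisons by the values below. In this mean 0 genes passed edgeR's quasi-likelihood test (217 at an unadjusted p under 0.05), with 0 by DESeq2 and 0 by limma-voom, and 1 by edgeR without FNLN 1 kPa replicate 3. The largest log2 difference among 11276 genes with a mean of at least 2 log2 CPM was 0.58, against 0.91 for C4TC with C1FN and 1.03 for FNLN with C4TC. ACTA2 differed by 0.08, COL1A1 by 0.06, FN1 by 0.09 and LAMB1 by 0.04 on the log2 scale. Basement membrane genes were slightly higher on FNLN as a list (median 0.09; camera, adjusted p = 0.000189; adjusted p = 0.886 with an estimated correlation). Its named members had fitted values of 0.18 (COL4A6), 0.09 (NID2), 0.18 (LAMB3) and 0.09 (AGRN), none of which passed, and 0 of 19 were called when adjusted over the list alone.

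For FNLN against C4TC the pattern of contractile genes was seen again, in a comparison that shares the C4TC libraries. Averaged over stiffness, 0 genes passed edgeR's quasi-likelihood test (337 at an unadjusted p under 0.05), with 1 by DESeq2 and 0 by limma-voom; edgeR called 8 without C4TC 1 kPa replicate 1. The contractile list was higher on FNLN, with a median of 0.26 (camera, adjusted p = 1.43e-18; adjusted p = 0.149 with an estimated correlation) and fitted values of 1.03 (ACTG2), 0.66 (CNN1), 0.72 (ACTA2, SE 0.24) and 0.48 (MYLK), each with an adjusted p of 1. Its median was 0.03 at 25 kPa and 0.47 at 1 kPa, where ACTA2 was at 469.8 ± 127 CPM on FNLN (SD, n = 3). TNC, the gene of a C4TC substrate protein, had a fitted log2 fold change of 0.40 (unadjusted p = 0.00247, adjusted p = 1), and at 1 kPa of 0.78 (unadjusted p = 0.000138, adjusted p = 0.451, edgeR). Cholesterol genes were lower on FNLN as a list (median -0.15; camera, adjusted p = 2.59e-11; adjusted p = 0.356 with an estimated correlation), with FDPS at -0.17 and CYP51A1 at -0.15, and a median of 0.01 at 25 kPa and -0.33 at 1 kPa. Both list calls held in the 18 fits without 1 library.

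Other list differences between FNLN and C4TC were smaller and rested on single libraries. The camera calls were for YAP/TAZ target genes (median 0.12, adjusted p = 0.00131; adjusted p = 0.659 with an estimated correlation), matrix glycoproteins and proteoglycans (0.12, 0.00336; 0.659), cell cycle genes (0.13, 0.00167; 0.659), cytokines and inflammatory genes (-0.08, 0.0468; 0.659), cholangiocyte markers (-0.13, 0.0102; 0.149) and smooth muscle and pericyte markers (0.13, 0.0285; 0.356). YAP/TAZ and cell cycle calls ended without C4TC 1 kPa replicate 2 (0.842 and 0.926) or FNLN 1 kPa replicate 1 (0.458 and 0.334), and the latter also without FNLN 25 kPa replicate 1 (0.706). The glycoprotein call ended without FNLN 25 kPa replicate 3 (0.076), C4TC 1 kPa replicate 2 (0.276) or FNLN 1 kPa replicate 3 (0.325). Cholangiocyte markers were no longer called without FNLN 25 kPa replicate 3 (0.0579), C4TC 1 kPa replicate 1 (0.0552) or FNLN 1 kPa replicate 2 (0.101). Smooth muscle markers were not called without C4TC 25 kPa replicate 1 (0.097), FNLN 25 kPa replicate 3 (0.0795), or FNLN 1 kPa replicate 1 (0.0724) or 3 (0.166). The cytokine call ended without any of 8 libraries, with adjusted p up to 0.927 without FNLN 1 kPa replicate 1; these were C1FN 25 kPa and 1 kPa replicates 3, C4TC 25 kPa replicate 1, FNLN 25 kPa replicates 2 and 3, C4TC 1 kPa replicate 2 and FNLN 1 kPa replicates 1 and 3. No member passed edgeR's test; the named ones had fitted values of 0.30 (NUAK2), 0.10 (ARHGEF17), 0.12 (RBMS3), 0.14 (PTPN14), -0.20 (SPP1), 0.15 (LTBP1), 0.39 (ELN), 0.11 (MCM3), 0.27 (KIF20A), 0.19 (AURKA) and 0.28 (MKI67), and of -0.36 (TNFAIP6), -0.32 (IL1A), -0.53 (CCL7), -0.32 (BIRC3), -0.30 (CD24), -0.43 (SOX9), -0.07 (ANXA4), 0.14 (CSPG4), 0.16 (RGS5) and 0.11 (MCAM). These values moved with single libraries, MKI67 from 0.027 without FNLN 1 kPa replicate 1 to 0.592 without C4TC 1 kPa replicate 1, and BIRC3 from -0.583 without FNLN 1 kPa replicate 2 to -0.073 without C4TC 1 kPa replicate 2.

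At a single stiffness the ECM pairs were also compared with 3 libraries against 3. At 25 kPa edgeR's quasi-likelihood test called 0 genes for C4TC against C1FN (255 at an unadjusted p under 0.05; 2 by DESeq2, 0 by limma-voom, 1 by edgeR without C1FN 25 kPa replicate 3) and 0 for FNLN against C1FN (235; 0 by DESeq2 and 0 by limma-voom). At 1 kPa it called 0 for C4TC against C1FN (649; 3 by DESeq2, 0 by limma-voom, 31 by edgeR without C4TC 1 kPa replicate 1) and 0 for FNLN against C1FN (140; 0 by DESeq2, 0 by limma-voom, 1 by edgeR without FNLN 1 kPa replicate 3). For FNLN against C4TC at 1 kPa it called 0 (714; 13 by DESeq2, 0 by limma-voom), with 76 without C4TC 1 kPa replicate 1 and 1 without FNLN 1 kPa replicate 3. The median SE was 0.152 at a single stiffness and 0.108 for the means. In counts simulated on these libraries, edgeR recovered 80% of 2-fold and 46% of 1.5-fold changes for C4TC against C1FN at 1 kPa, and 88% and 60% for the mean of both stiffnesses. The simulation gave each gene the same spread in all groups and no effect of the replicate number. The real soft libraries varied more (median SD of log2 CPM over genes 0.211 for C4TC at 1 kPa and 0.118 at 25 kPa). The shares recovered at 1 kPa may therefore be too high. The tests on the real libraries also used 1 spread per gene over all groups. Their SE and p-values may thus be too small at 1 kPa and too large at 25 kPa.

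The only gene that edgeR with all 18 libraries called between ECM pairs was the antisense gene AC017083.2 (ENSG00000273275.1; chromosome 2, 68179833 to 68180532, plus strand, hg38), within PPP3R1, which encodes a calcineurin subunit on the other strand. In FNLN against C4TC at 25 kPa it was at 3.21 ± 0.475 and 0.355 ± 0.0285 CPM (SD, n = 3; log2 fold change 3.16, SE 0.45, adjusted p = 0.0489, edgeR). At 1 kPa it was at 2.74 ± 0.743 CPM on FNLN and 3.25 ± 0.235 CPM on C4TC, and on C1FN at 2.14 ± 1.39 CPM at 25 kPa and 3.35 ± 1.37 CPM at 1 kPa. It lies outside the rule for named genes and was chosen after its values were seen. Whether the counting used strand is not given in the sources used here, so its reads and those of PPP3R1 cannot be told apart. Its call held without C1FN 25 kPa replicate 2 or 3 or C1FN 1 kPa replicate 1 or 2, and without any other single library 0 genes were called. With library size only, with quality weights or without the libraries numbered 2, of which the latter 2 were chosen after the data were seen, 0 genes were called. DESeq2 called 2 genes and limma-voom 0 in this comparison, and 155 had an unadjusted p under 0.05.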

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

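The fits without the libraries numbered 2, with quality weights, and with a block joined to an estimated correlation or to fry were chosen only after the results were seen. Of 4904 values of named genes under other settings, 4806 kept direction and side of the threshold, 55 lost their call, 39 gained one and 4 changed sign: CDH5 at -0.01 with quality weights, COL1A1 at -0.068 and COL4A1 at -0.13 without the libraries numbered 2, and COL4A1 at -0.002 without C4TC 1 kPa replicate 2. None of these 4 was called; COL4A1 ranged from -0.002 to 0.186 without 1 library, highest without C4TC 1 kPa replicate 1. Of 98 named calls in the stiffness mean, 94 held in each fit without 1 library (all but CCN2, DDB2, IFI27 and IFIT2). The stiffness mean gave 5789 to 6959 genes without 1 library, against 6442, and 5229 without the libraries numbered 2. Stiffness on C1FN gave 1809 genes, 381 without the libraries numbered 2 and 745 to 2173 without 1 library (745 without C1FN 1 kPa replicate 2, 886 without C1FN 25 kPa replicate 2, 1068 without C1FN 25 kPa replicate 1). On C4TC there were 3692, 2086 with only the groups compared, 2285 without the libraries numbered 2, 6648 with quality weights and 2136 to 4613 without 1 library (lowest without C4TC 1 kPa replicate 3). On FNLN there were 1355, 829 with only the groups compared and 829 also without the libraries numbered 2, 3088 with quality weights and 614 to 1708 without 1 library (614, 722 and 768 without FNLN 25 kPa replicates 3, 1 and 2, 651 without FNLN 1 kPa replicate 3). For these changes the cause was not tested. For the replicate block, 18 of 18 libraries correlated best on average with their own number. The 45 correlations between same-numbered libraries ran from 0.027 to 0.426 (median 0.126), against a median of -0.076 between different numbers. Of the 45, 15 were at or under 0.1, so the other comparisons did not meet that check. Their same-numbered libraries were still more alike than others, so the check does not show that they are unpaired. With the block the stiffness mean was 8007, C1FN 3528, C4TC 5478, FNLN 2865, FNLN against C4TC at 25 kPa 0 (its gene at an adjusted p of 0.0963), and every other ECM comparison and the interaction stayed at 0. C4TC against C1FN gave 0 to 4 genes without 1 library as the mean, 0 to 1 at 25 kPa (2 by DESeq2, 1 with only the groups compared) and 0 to 31 at 1 kPa (3 by DESeq2). FNLN against C1FN gave 0 to 1 as the mean, 0 at 25 kPa and 0 to 1 at 1 kPa. FNLN against C4TC gave 0 to 8 as the mean (1 by DESeq2, 1 with only the groups compared, 3 with quality weights) and 0 to 76 at 1 kPa (13 by DESeq2, 72 with quality weights). At 25 kPa its single gene became 2 by DESeq2, 0 to 1 without 1 library (1 without C1FN 25 kPa replicates 2 or 3 or C1FN 1 kPa replicates 1 or 2), and 0 with library size only, limma-voom, quality weights or the libraries numbered 2 left out. The interaction gave 2 genes by DESeq2 and 0 to 1 without 1 library. The values 4, 31, 8, 76 and the interaction's 1 came without C4TC 1 kPa replicate 1, and those of 1 without C1FN 25 kPa replicate 3 (C4TC against C1FN) or FNLN 1 kPa replicate 3 (FNLN against C1FN); the cause was not tested. Camera called 11 lists for the stiffness mean, 11 on C1FN, 12 on C4TC, 11 on FNLN, 5 for C4TC against C1FN, 1 for FNLN against C1FN and 8 for FNLN against C4TC. With an estimated correlation, alone or with the replicate block, it called 0 in each of the 7. The fry test called 13, 8, 10 and 7 for stiffness and 0, 0 and 0 for the ECM pairs, and with the replicate block 16, 13, 12 and 11 for stiffness and 0 for each ECM pair. Without 1 library camera called 11 to 13, 9 to 12, 10 to 12, 10 to 13, 4 to 9, 1 to 5 and 4 to 12 lists in the same order. For C4TC against C1FN it was 9 without C1FN 1 kPa replicate 2 and 8 without C4TC 1 kPa replicate 1; for FNLN against C4TC 4 without FNLN 25 kPa replicate 3 or FNLN 1 kPa replicate 1. For FNLN against C1FN it was 5 without C1FN 25 kPa replicate 3 or FNLN 1 kPa replicate 2, 4 without FNLN 1 kPa replicate 1 or 3, 3 without C1FN 25 kPa replicate 1 or C1FN 1 kPa replicate 2, and 2 without FNLN 25 kPa replicates 1 or 3 or C1FN 1 kPa replicates 1 or 3.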

Other observations

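The 9 gene lists described first, and for the libraries numbered 2 the tests of depth, shared batch, both correlations and the slopes, and for the ribosomal and respiratory genes the test of the share of abundant genes, were chosen only after the results were seen. The 3 patterns weighed below were also noticed in these results. Complement genes were lower at 25 than at 1 kPa: of 16 tested, 10 fell and 0 rose (edgeR's quasi-likelihood test; median log2 fold change -0.46). C3, the central complement protein, was at 9.54 ± 2.24 CPM at 25 kPa and 62.8 ± 17.8 CPM at 1 kPa (SD, n = 9; log2 fold change -2.71, adjusted p = 9.86e-08, edgeR), with CFB at -2.21, C1R at -1.22 and C1S at -1.25. In prostaglandin synthesis 4 of 8 genes fell, among them the cyclooxygenases PTGS2 (-3.86; 23.4 ± 13 and 346 ± 179 CPM) and PTGS1 (-1.57) and the prostaglandin E synthase PTGES (-2.76), while the prostacyclin synthase PTGIS rose (0.80). Lysosomal genes fell in 37 of 43 cases and rose in 0 (median -0.44), with the collagen-degrading cathepsin CTSK at -1.04, CTSD at -0.80, GPNMB at -1.45 and LAMP1 at -0.40. Of 22 nuclear receptors of the NR4A family and immediate early genes, 13 fell and 1 rose; NR4A1 (-2.29), NR4A2 (-3.65) and NR4A3 (-3.15) fell most. These 4 lists passed camera also with an estimated correlation (adjusted p = 0.00802, 0.00935, 0.00935 and 0.00802), but they were picked because their members had been seen to move, so these p-values are not independent evidence. Medians had the same sign under RLE factors and library size only.

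Keratin genes were higher on the stiff substrate in 6 of 10 cases and lower in 1 (KRT81, -0.72), with KRT34 at 1.88, KRT18 at 1.65 and KRT14 at 1.32 (median 0.79; adjusted p = 0.0911 with an estimated correlation). Class I antigen presentation genes fell in 7 of 16 cases and rose in 1 (median -0.12; adjusted p = 0.119 with an estimated correlation). Ribosomal protein genes were higher in 67 of 78 cases and lower in 0 (median 0.23; adjusted p = 0.136), mitochondrially encoded genes in 10 of 13 and 0 (0.31; adjusted p = 0.237), and nuclear genes of oxidative phosphorylation in 49 and 3 of 84 (0.18; adjusted p = 0.237, each with an estimated correlation). MT-CO1 was at 10640 ± 622 CPM at 25 kPa and 7781 ± 633 CPM at 1 kPa (log2 fold change 0.45).

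This small shared rise of 175 ribosomal and respiratory genes was weighed against technical causes. Its pooled median was 0.207 with TMM factors. Length and GC content explained 0.445% of the variance of the fold changes and their trend put these genes at 0.021 (median 0.212 after a regression), which argues against them as the whole cause. Abundant genes were argued against by their share: the 10 most counted could raise the remaining counts by at most 0.039 between any stiff and any soft library, while leaving them out of the library sizes (0.218) moved too little to decide. Scaling stays open, since RLE factors and library size only (lower value 0.203) moved the median of all genes from 0.016 only to 0.012 and 0.019 and the files hold almost no spike-in counts; a biological response was not tested.

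At 1 kPa the libraries numbered 2 lay farthest from the stiff ones in all 3 ECM pairs. Lower depth would predict the lowest total in each soft group, which held in 1 of 3. Hepatocytes or leukocytes would bring their abundant transcripts, but 8 markers summed to at most 8.51 CPM in these libraries, mostly APOA1, with ALB at 0. A batch shift of equal size at both stiffnesses was argued against for this gap, which was -2.6 at 25 kPa and -26.7 at 1 kPa on the first component, although on the second the replicate numbers lay apart at both stiffnesses. Whether the same stiffness genes moved farther stays open. The slope of number 2 on the changes of the other numbers was the highest in all 3 pairs (lowest ratio 1.11). That of number 1 was the lowest (0.44, 0.56 and 0.41 on C1FN, C4TC and FNLN). The rank of number 2 met its prediction but largely restates the first component, with other reference genes for each number. Correlations across 11276 genes decided nothing (0.23, -0.04 and -0.23, and 0.23, -0.06 and -0.21 with the stiff library subtracted). The soft libraries numbered 1 lay nearest the stiff ones in all 3 pairs. On C4TC, number 3 (-51.08 on the first component) lay closer to number 2 (-61.95) than to number 1 (-15.58). No donor, culture or day was given to test.

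The median of the contractile genes was lower on C4TC than on the other ECM pairs at 1 kPa, where camera was not run, and no member passed edgeR's test. A single library was not the source: the list's median difference was -0.15, -0.6 and -0.65 in replicate numbers 1, 2 and 3, against 0, 0.01 and -0.12 at 25 kPa. An exact one-sided permutation of the ECM pairs within replicate numbers gave p = 0.037, the smallest it can give, for a difference of -0.66 between means, not medians, over the list, with C4TC picked as the pair to test from these data. Over both stiffnesses the list's camera calls ended with an estimated correlation (adjusted p = 0.691 against C1FN and 0.149 against FNLN). Uneven cell density or attachment on the C4TC spots was not tested and stays open.

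Other splits of the libraries were compared with the real ones. For the stiffness mean, 1 of 100 splits, the real one, gave as many genes (6442, highest other 4760), which is the smallest share that 100 splits can give. A random split of these libraries within ECM pairs was thus unlikely to give as many. The splits ignored the replicate numbers and cannot tell whether the libraries are independent cultures. The split with 4760 exchanged a single soft library (C1FN 1 kPa replicate 1) with a single stiff one (C1FN 25 kPa replicate 3), and the next highest gave 1744. For the ECM means the real count was 0, which all 100 of 100 splits reach by construction, so the splits say nothing about chance there. The highest others were 375 for C4TC against C1FN, 5 for FNLN against C1FN and 334 for FNLN against C4TC. The 375 and 334 point to a structure of the libraries, since the split with 375 put all 4 libraries numbered 1 on the same side and the 15 splits of C4TC and C1FN that part as many same-numbered pairs as the real one gave at most 0. For the interaction the real count was also 0, reached by 100 of 100 splits. Its highest other, 3819, came in a split that kept the stiffness labels of C1FN and reversed all those of C4TC. The stiffness change itself then enters as an interaction, so this count does not point to other structure.

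With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For stiffness on C1FN, C4TC and FNLN the real split gave 1809, 3692 and 1355 genes and was 1 of 10 with as many, with 0 as the highest other in each. For C4TC against C1FN the real 0 stood beside a highest other of 0 at 25 kPa and 1553 at 1 kPa, and for FNLN against C1FN beside 1 at 25 kPa and 17 at 1 kPa, so that 10 of 10 gave as many. For FNLN against C4TC the real 1 at 25 kPa stood beside 0, and the real 0 at 1 kPa beside 2161. The splits with 1553 and 2161 set the library numbered 2 of each pair against those numbered 1, each with 1 library numbered 3, and point to structure. The 3 splits that part every same-numbered pair gave 0 in both, the comparisons at 1 kPa whose numbers pair the libraries.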
